A study of Mus musculus with 24 samples.

How the data were processed

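Gene expression was measured on a NanoString nCounter immune panel in 24 samples of CD4+ T cells from young (2 to 3 months) and aged (22 to 24 months) mice, sorted per the labels into Treg and non-Treg. The deposited values are log2 counts that the authors had multiplied by 1 factor per sample; how that factor was set, and whether background was subtracted, is not stated. Within each sample, 2 to the power of each value was a whole multiple of a single step (0.6275 to 2.6266, tolerance 0.02, genes under 1000 counts), in 100% of genes, so whole counts and total counts per sample were recovered from it. Counting error was therefore small for most tested genes, but low values were near an unknown background. Control probes were not analysed here, and of the planned housekeeping genes only Abcf1 was in the table. Values below 20 were treated as dim: where all libraries of 1 group lay below 20, a fold is given as a lower bound against 20, and no fold where neither group reached it. Where only a group's mean lay below 20, the value with values under 20 set to 20 is given too.

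Gene names were matched to mouse symbols by the RefSeq gene table (531 by symbol, 13 by an older name, 3 unmatched). No genome coordinates were used here. Of 547 genes, 391 reached 20 in at least 5 samples, the size of the smallest group, and were tested; 156 were left out. limma 3.58.1 in R 4.3.3 fitted the mean of each of the 4 groups with the title series as a covariate to all 24 samples (residual degrees of freedom 19, prior 1.62), with Benjamini-Hochberg adjusted p-values under 0.05 called. The 5 comparisons were Treg against non-Treg at each age, aged against young in each cell type, and the difference of the age effects. The replicate pairs of a group were tested for being repeats of 1 library by their counts; the lowest chi-square per degree of freedom of 25 pairs was 2.43, and none were merged. The sort genes were compared by exact two-sided permutation tests over all 792 or 924 splits.

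Of the 20 gene lists and 10 lists of other cell types written beforehand, 25 with at least 3 tested members were tested by camera with a preset correlation of 0.01, adjusted within each comparison (125 tests in all), with an estimated correlation and with fry as alternatives. The gene lists were Treg identity, naive and central memory, effector and memory, Th1, Th2, Th17, follicular helper, co-inhibitory, cytotoxicity and natural killer receptors, interferon response, NF-kB, T cell receptor signalling, AP-1, apoptosis, cell cycle, chemokine receptors, cytokines, class I presentation, Jak-STAT and TGF-beta. The other cell types were B, plasma, monocyte, neutrophil, dendritic, natural killer, CD8, gamma-delta, erythroid and stroma; of the gamma-delta list 0 genes were in the table. Named genes followed a rule: the 12 largest called changes in each direction of each pairwise comparison, up to 4 members per list with the smallest adjusted p, 5 per direction for the difference of age effects, and 12 genes in every pairwise comparison (Foxp3, Il2ra, Tnfrsf18, Cd4, Ifng, Il10, Il17a, Il21, Tnf, Ctla4, Pdcd1 and Ikzf2). Not all genes that the rule names are described. Groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

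Alternatives were median centring, centring on Abcf1, quantile normalization, a floor of 50 in at least 5 samples, no filter, a pseudocount of 10, no series covariate, each title series alone, sample weights, a mean-variance trend, a fit over the compared groups only and each library left out in turn. Leaving out aged Treg replicates 4 and 6, setting values under 20 to 20, pairing Treg and non-Treg libraries by their order within each age and title series (limma duplicateCorrelation), and each title series for the correlation of the age effects were added after seeing the data. Simulated data of the same size and spread, with 200 of 391 genes changed in 20 repeats, were used to check the fit: a log2 change of 1 was recovered in 85.9% or more and one of 0.5 in 64.0% or more of changed genes, with 2.46% to 2.55% of calls false. Dixon's test was applied to each named gene in each group compared that had a library at 20 or more, and to each library's total count, median, lower quartile and number of genes at 20 or more. For each comparison, 100 splits of the same samples into groups of the same sizes, the real one included, were fitted again. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.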

Results

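The data held 547 immune genes measured by NanoString nCounter, a method that counts RNA molecules with colour-coded probes, in 24 samples of CD4+ T cells from female C57BL/6 mice. Regulatory T cells (Treg, sorted as CD4+CD25+GITR+) and the CD4+CD25−GITR− cells left beside them (non-Treg) were compared at 2 to 3 months (young) and at 22 to 24 months (aged). Their source was a pool of spleens and of the lymph nodes that drain the eye and the lacrimal gland. There were 7 young Treg, 5 young non-Treg, 6 aged Treg and 6 aged non-Treg samples. The 2 series of sample titles (DP20323 and DP182, 12 samples each) both held all 4 groups. Total counts per sample had a median of 825440. They ranged from 316259 to 1112829 in aged Treg, 814686 to 1279876 in aged non-Treg, 453259 to 807392 in young Treg and 523970 to 1020252 in young non-Treg. Of the 547 genes, 391 were tested. The p-values measure only the spread between these samples, since nothing states that each came from a separate pool of mice.

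Values after ± are standard errors of log2 fold changes, unless marked SD. Where a group's mean lay below 20, the value marked floored has values under 20 set to 20. The direction of small effects depended on scaling. Setting the medians of all libraries equal (median centring) shifted every log2 fold change by −0.75 for Treg against non-Treg in young mice, −0.20 in aged mice, −0.32 for age in Treg and −0.86 for age in non-Treg. Centring on Abcf1, the only planned housekeeping gene in the table, shifted them by −0.12, 0.02, 0.26 and 0.11 in that order. Both centrings shift all genes alike by less than 2-fold. Genes that changed by 2-fold or more (115, 125, 109 and 147 genes) therefore could not turn under either, and their kept direction is no test. Quantile normalization, which does not shift all genes alike, turned 0, 0, 0 and 6 of these genes. Gene lists were fixed beforehand. Their counts adjusted over the list alone equalled the counts over all tested genes in these 4 comparisons, except for Th17 genes with age in Treg and for B cell genes in aged mice and with age in non-Treg, where both are given. Of the 12 list calls made with camera's preset correlation, 1 held with an estimated correlation: Treg identity genes in young mice.

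The sort was first checked on the genes behind it. Foxp3, the transcription factor that defines Treg, had a mean log2 count of 13.30 ± 0.09 (SD, n = 7) in young Treg and 6.44 ± 1.08 (SD, n = 5) in young non-Treg (exact two-sided permutation p = 0.0013). In aged mice its means were 13.15 ± 0.16 (SD, n = 6) in Treg and 6.15 ± 0.64 (SD, n = 6) in non-Treg (exact permutation p = 0.0022). Il2ra, which encodes CD25, had means of 13.86 ± 0.14 (SD, n = 7) in Treg and 7.71 ± 0.94 (SD, n = 5) in non-Treg of young mice. In aged mice they were 12.97 ± 0.20 and 8.0 ± 0.33 (SD, n = 6 each), with the same exact p-values. Cd4 was lower in Treg, at 12.14 ± 0.19 (SD, n = 7) against 12.55 ± 0.15 (SD, n = 5) in young mice (exact p = 0.0025) and at 12.46 ± 0.17 against 12.99 ± 0.11 (SD, n = 6 each) in aged mice (exact p = 0.0022). The gene for GITR was not in the table. Young non-Treg replicate 4 had the highest Foxp3 (8.10) and Il2ra (9.03) of its group.

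**Figure D1:**
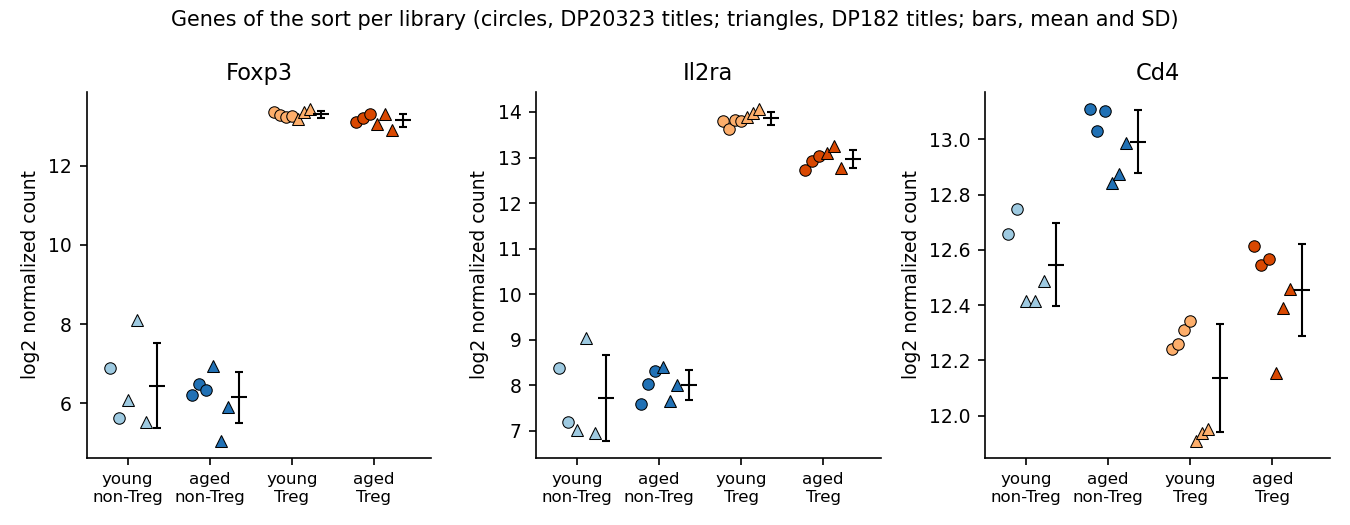
Log2 normalized counts of Foxp3, Il2ra and Cd4 in each library, by group (circles, DP20323 titles; triangles, DP182 titles; bars, mean and SD). Foxp3 lies at 12.90 or more in all Treg libraries and at 8.10 or less in all non-Treg libraries.

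Treg against non-Treg in young mice asked what set regulatory cells apart before ageing. Young Treg expressed Foxp3 115-fold more (log2 fold change 6.85 ± 0.34, n = 7 against 5) and Il2ra 71.6-fold more (6.16 ± 0.27). Ikzf2, which encodes the Treg factor Helios, was 27.5-fold higher (4.78 ± 0.13), the costimulatory receptor OX40 (Tnfrsf4) 19.3-fold (4.27 ± 0.12) and the inhibitory receptor Tigit 15.7-fold (3.97 ± 0.16). The killer lectin receptor Klrd1 fell by 4.42 ± 0.59 (floored 4.08) and Cd40lg, the helper signal to B cells, by 2.15 ± 0.15. In all, 187 of 391 genes were higher in Treg and 55 lower (limma, adjusted p under 0.05), and 94 and 21 of these differed by 2-fold or more.

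All 23 measured Treg identity genes were higher in young Treg (21 after median centring). Camera gave an adjusted p = 2.01e-10, and adjusted p = 0.0184 with an estimated correlation. Besides those above, Ctla4, which restrains costimulation, rose by 3.76 ± 0.42, Ebi3, a subunit of interleukin-35, by 4.36 ± 0.15 and Cd83 by 5.41 ± 0.17. The suppressive cytokine Il10 was at least 5.8-fold higher. The largest increases also included the decoy interleukin-1 receptor Il1r2 (at least 21.6-fold), the chemokine receptors Ccr8 (5.68 ± 0.62, floored 4.42) and Ccr6 (5.03 ± 0.31), the TNF receptor family member Tnfrsf8 (at least 10-fold) and the kinase Src (4.49 ± 0.22, floored 3.82). Of 13 co-inhibitory genes, 8 were higher, 1 lower and 4 not past the threshold (7 higher and 2 lower after median centring). Pdcd1, which encodes PD-1, rose by 2.15 ± 0.25, its ligand Pdcd1lg2 by 2.80 ± 0.21 and the ectonucleotidase Entpd1 by 3.36 ± 0.22.

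Helper lists were mixed in young mice. Th2 genes gave 4 higher, 1 lower and 4 not past (4 and 3 after median centring), with the interleukin-33 receptor Il1rl1 at 3.71 ± 0.27 (floored 3.41), Ccr4 at 2.10 ± 0.15 and Gata3, the Th2 master factor, at 1.13 ± 0.13. Th17 genes gave 6 higher, 0 lower and 6 not past (5 and 3 after median centring), with Ahr at 2.22 ± 0.17. Follicular helper genes gave 8 higher, 1 lower and 2 not past (5 and 4), with Maf at 1.93 ± 0.16 and the follicle-homing receptor Cxcr5 at 1.82 ± 0.20. Th1 genes gave 4 higher, 2 lower and 11 not past, but 2 higher and 10 lower after median centring, with Lta at 1.61 ± 0.09 and Il12rb1 at 2.01 ± 0.17. Effector and memory genes gave 7 higher, 5 lower and 6 not past (4 and 9), with the interleukin-2 receptor chain Il2rb at 3.41 ± 0.15. Among cytokines, 9 of 20 tested genes were higher, 1 lower and 10 not past (7 and 10), with the macrophage growth factor Csf1 at 3.41 ± 0.17.

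Of 14 cytotoxicity and natural killer receptor genes, 2 were higher in young Treg, 7 lower and 5 not past (1 and 8 after median centring; camera adjusted p = 0.0153, but adjusted p = 0.379 after median centring and adjusted p = 0.915 with an estimated correlation). Prf1, which encodes perforin, fell by 2.16 ± 0.22, Klrc1 by 2.32 ± 0.60 (floored 2.03), Klrk1 by 1.78 ± 0.45 (−2.73 and −1.01 in the DP20323 and DP182 titles) and the death ligand Fasl by 1.32 ± 0.29. Naive and central memory genes gave 3 higher, 5 lower and 3 not past (0 and 9 after median centring; camera adjusted p = 0.0852, and adjusted p = 0.915 with an estimated correlation), with the naive T cell factors Tcf7 at −1.42 ± 0.08 and Lef1 at −1.35 ± 0.13 and the lymph node homing receptor Ccr7 at −0.97 ± 0.18. Chemokine receptor genes gave 5 higher, 2 lower and 10 not past, but 4 higher and 8 lower after median centring, with Cxcr6 at −2.15 ± 0.48. Other large decreases were App (−3.60 ± 0.25), Il1rl2 (−2.56 ± 0.19), the collagen receptor Lair1 (−1.98 ± 0.40), Plaur (−1.82 ± 0.63) and the Fc receptor Fcgrt (−1.76 ± 0.34, floored −1.52). Without young non-Treg replicate 2 Plaur was −1.35 (adjusted p = 0.0791).

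Several markers of other cells were also higher in young Treg libraries: 6 of 14 B cell genes (4 after median centring), all 4 plasma cell genes (2), 3 of 6 dendritic cell genes (2), 2 of 4 monocyte genes with 1 lower (1 and 1), and 1 of 3 neutrophil genes with none lower (1 and 1). Among them were the B cell receptor chain Cd79b (3.23 ± 0.20), the class II chaperone Cd74 (3.52 ± 0.31), the costimulator Cd80 (3.43 ± 0.20), the NADPH oxidase chain Cybb (3.42 ± 0.13) and the plasma cell and T cell factor Irf4 (1.90 ± 0.33). The neutrophil gene was Il1r2. Of 4 natural killer cell genes 1 was lower and none higher. Both tested stroma genes, Pecam1 and Thy1, which T cells express too, were lower, and neither the tested CD8 gene nor the 2 erythroid and platelet genes passed.

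Of the planned cytokines, Ifng was at 0.03 ± 0.24 (adjusted p = 0.930), Tnf at 0.06 ± 0.19 (adjusted p = 0.802) and Il21 at −0.57 ± 0.31 (adjusted p = 0.115). Il17a lay below 20 in 6 of 7 Treg and all 5 non-Treg libraries, so no fold is given (adjusted p = 0.739). Median centring and quantile normalization turned Ifng to −0.72 and −0.83 and Tnf to −0.68 and −0.63, and Il21 passed after both (−1.31 and −1.26) and without young non-Treg replicate 3 (−0.74, adjusted p = 0.0493). All 242 called genes had the same direction in both title series, and log2 fold changes correlated across genes between the series (r = 0.961; genes are not independent replicates). Groups did not overlap for 166 of the 242 genes and for 23 of the 24 largest, Plaur being the exception. Those genes were chosen by these same values, so chance gives no reference for them. Of all 391 tested genes, called or not, 167 did not overlap, where the chance share for a single gene is 0.253%. The higher share was 77.3% as scaled by the authors, 29.8% after median centring, 69.8% after centring on Abcf1 and 38.6% after quantile normalization. Of the 242 directions, median centring turned 71, quantile normalization 48 and Abcf1 none.

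Treg against non-Treg in aged mice put the same question to old animals. Aged Treg expressed Foxp3 128-fold more than aged non-Treg (6.99 ± 0.33, n = 6 against 6), Il2ra 31.4-fold more (4.97 ± 0.27) and the chemokine receptor Ccr8 at least 86.8-fold more. Among the largest differences the other way, Eomes, a master factor of cytotoxic and memory T cells, was 33.0-fold lower in Treg (−5.05 ± 0.41) and the chemokine Ccl5 16.1-fold lower (−4.0 ± 0.40). Of 391 genes, 174 were higher and 103 lower in aged Treg (limma), 81 and 44 of them by 2-fold or more.

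Treg identity genes gave 21 higher, 1 lower and 1 not past in aged mice (20 and 1 after median centring). Camera gave an adjusted p = 3.36e-08, but adjusted p = 0.0548 with an estimated correlation. The increases included Cd81 (4.20 ± 0.12), Ebi3 (4.20 ± 0.15), Ikzf4, which encodes the Treg factor Eos (4.0 ± 0.14), Cd83 (3.99 ± 0.17), the costimulator 4-1BB (Tnfrsf9, 3.81 ± 0.13), Tnfrsf1b (2.57 ± 0.09), Ikzf2 (2.30 ± 0.12), Tigit (1.62 ± 0.15) and Ctla4 (1.40 ± 0.42). The lower member was Gzmb, which encodes the cytotoxic protease granzyme B (−2.08 ± 0.53), and the one not past was Il10 (0.76 ± 0.57, adjusted p = 0.249). Il1rl1 (4.86 ± 0.26), Il1r2 (4.73 ± 0.40), Tnfrsf8 (3.85 ± 0.23) and the neutrophil chemokine Cxcl3 (at least 5.24-fold) were also among the largest increases. Co-inhibitory genes gave 7 higher, 4 lower and 2 not past (6 and 4 after median centring). Pdcd1 was at 0.11 ± 0.24 (adjusted p = 0.708).

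Of 14 cytotoxicity genes, 1 was higher in aged Treg, 11 lower and 2 not past, before and after median centring. Camera gave an adjusted p = 0.0012, but adjusted p = 0.607 with an estimated correlation. Prf1 fell by 3.0 ± 0.22 and Fasl by 2.86 ± 0.28. The receptors Klrd1 and Klrc1 both fell by 3.04, with standard errors of 0.58 and 0.59. In the DP182 titles they stood at −1.34 and −1.14, and in the DP20323 titles, where all 3 aged Treg libraries were below 20, the falls were at least 4.26 and 3.25. Effector and memory genes gave 4 higher, 10 lower and 4 not past (4 and 11 after median centring; camera adjusted p = 0.0524). The interleukin-18 receptor Il18r1 rose by 1.27 ± 0.12 and the integrin Itga4 fell by 0.97 ± 0.07. Th1 genes gave 4 higher, 8 lower and 5 not past (3 and 10), with Ifng, the Th1 cytokine, 5.68-fold lower (−2.51 ± 0.23) and Runx3 at −2.27 ± 0.27. Naive and central memory genes gave 1 higher, 9 lower and 1 not past (1 and 10). Camera gave an adjusted p = 0.0012, but adjusted p = 0.402 with an estimated correlation. Tcf7 stood at −1.80 ± 0.08, Il6ra at −1.65 ± 0.13 and Lef1 at −1.48 ± 0.12.

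Chemokine receptor genes gave 3 higher, 8 lower and 6 not past in aged mice (3 and 9 after median centring), with Ccr6 at 3.22 ± 0.31 and Cxcr6 at −2.95 ± 0.47 (−4.53 and −1.37 in the DP20323 and DP182 titles). Follicular helper genes gave 2 higher, 7 lower and 2 not past, before and after median centring, with Cd40lg at −2.18 ± 0.14 and Il21, the follicular helper cytokine, at −1.21 ± 0.30 (−2.15 and −0.26 by title series). Th2 genes gave 5 higher, 1 lower and 3 not past (5 and 2), with Ccr4 at 1.0 ± 0.15 and Gata3 at 1.03 ± 0.13. Th17 genes gave 5 higher, 2 lower and 5 not past (5 and 3), with Ahr at 2.14 ± 0.17. Cytokine genes gave 8 higher, 4 lower and 8 not past, but 6 higher and 7 lower after median centring. The chemokine genes Ccl3 (−3.78 ± 0.56; −5.04 and −2.52 by title series) and Ccl4 (−3.58 ± 0.50) and the receptor Lair1 (−3.16 ± 0.40) were also among the largest decreases.

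Other-cell markers moved with the aged Treg libraries too: 8 of 14 B cell genes were higher and 2 lower (8 and 2 after median centring; 9 and 2 adjusted over the list alone), and all 4 plasma cell genes were higher. So were 2 of 4 monocyte genes, 2 of 3 neutrophil genes, 1 CD8 gene, 1 of 2 erythroid and platelet genes (0 after median centring) and 3 of 6 dendritic cell genes with 1 lower. Of 4 natural killer cell genes 2 were lower, as were both stroma genes. Cd74 (3.80 ± 0.31), Cd79b (3.55 ± 0.20), the class II gene H2-Eb1 (3.32 ± 0.41; 2.26 and 4.39 by title series) and Cd40 (at least 3.7-fold) were among the higher genes. The neutrophil alarmin S100a8 reached 20, among the aged libraries, only in Treg replicates 4 (8.64) and 6 (10.40), and its call was lost without both (adjusted p = 0.119). Aged Treg replicate 4 stood apart in its low values, with a lower quartile of 7.17 against 2.79 to 4.59 in the other 23 libraries, and 520 genes at 20 or more against 312 to 418. Without aged Treg replicates 4 and 6, both chosen after the data were seen because they carried raised markers of other cells, 160 genes were higher and 116 lower, and 256 of the 277 calls remained.

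Tnf was at −0.25 ± 0.19 (adjusted p = 0.247) and Il17a at −0.45 ± 0.44 (adjusted p = 0.387) in aged mice, but Tnf passed after median centring (−0.45, adjusted p = 0.0396), and Il17a without aged Treg replicate 4 (−0.86, adjusted p = 0.0431) and after quantile normalization (−1.04). Of the 277 called genes, 275 had the same direction in both title series (r = 0.878 across genes). The groups did not overlap for 138 of the called genes and for 21 of the 24 largest, the exceptions being Ccl3, Klrd1 and Klrc1. Those genes were chosen by these same values. Of all 391 tested genes, called or not, 138 did not overlap, where the chance share for a single gene is 0.217%. The higher share was 62.8% as scaled by the authors, 48.1% after median centring, 63.6% after centring on Abcf1 and 45.1% after quantile normalization, with 9 directions turned by each of median centring and quantile normalization.

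**Figure D2:**
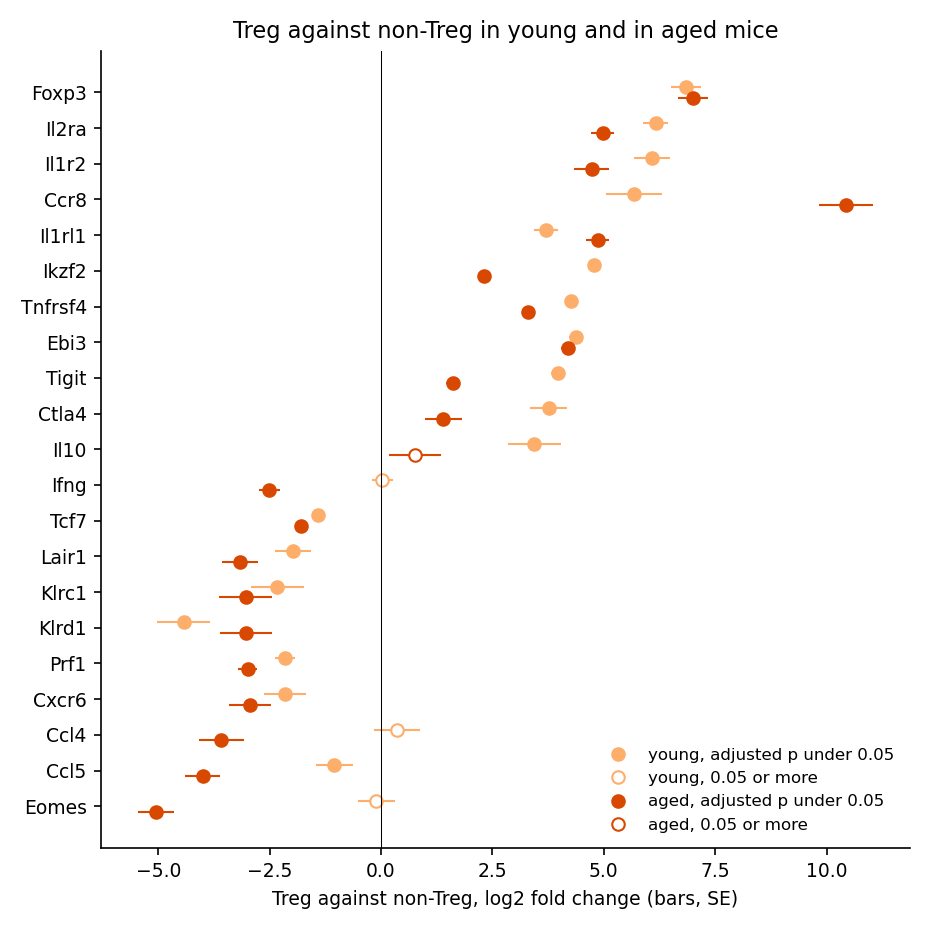
Log2 fold change of Treg against non-Treg in young and in aged mice for 21 genes (bars, SE; filled, limma adjusted p under 0.05). Foxp3 differs alike at both ages (6.85 and 6.99), while Eomes passes in aged and not in young mice (interaction −4.94); the fitted values of Ccr8 in aged and of Il1r2 and Il10 in young mice rest on non-Treg libraries below 20, and Ifng in young mice turns from 0.03 to −0.72 after median centring.

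Aged against young Treg asked what ageing changed in regulatory cells. Foxp3 was at −0.15 ± 0.32 (adjusted p = 0.700, n = 6 against 7). The interleukin-6 receptor Il6ra fell 4.66-fold (−2.22 ± 0.12) and the lymph node homing receptor Ccr7 3.83-fold (−1.94 ± 0.17). The inhibitory receptor Lilrb4a rose 27.1-fold (4.76 ± 0.38), the class II gene H2-Eb1 20.5-fold (4.36 ± 0.40) and Il21, a cytokine that drives B cell help, 10.7-fold (3.42 ± 0.29). The young Treg mean of H2-Eb1 (4.54) lay near the limit of 20 counts, so its fold is uncertain. Young Treg replicate 5 was at 6.14 and the next highest at 4.78. Without aged Treg replicates 4 and 6 the rise of H2-Eb1 was 4.07. Il2ra, the gene of the sorted marker CD25, fell 1.86-fold (−0.90 ± 0.26, adjusted p = 0.0043). Of 391 genes, 192 were higher and 62 lower (limma), 93 and 16 by 2-fold or more.

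Naive and central memory genes gave 9 lower, 1 higher and 1 not past (10 lower and 0 higher after median centring). Camera gave an adjusted p = 3.27e-07, but adjusted p = 0.0594 with an estimated correlation. Lef1 fell by 1.79 ± 0.12. Among the other large decreases, the survival gene Bcl2 fell by 1.35 ± 0.10, the adhesion genes Pecam1 by 1.68 ± 0.09 and Itga6 by 1.49 ± 0.11, the gut-homing receptor Ccr9 by 2.05 ± 0.40 (2.63 and 1.43 by title series) and the complement regulator Cd55 by 1.72 ± 0.15. The signalling adaptor Card9 (−2.25 ± 0.17, floored −1.89), the lymphoid factor Ikzf3 (−1.53 ± 0.10) and the interferon-gamma receptor chain Ifngr2 (−1.53 ± 0.14) were also lower. Treg identity genes gave 18 higher, 1 lower (Il2ra) and 4 not past (14 and 1 after median centring, 16 and 1 without aged Treg replicates 4 and 6). Camera gave an adjusted p = 0.0477, but adjusted p = 0.0514 with no series covariate and adjusted p = 0.947 with an estimated correlation. Prdm1, which encodes the effector factor Blimp-1, rose by 2.70 ± 0.19, Tigit by 2.56 ± 0.15, Cd81 by 1.76 ± 0.12, Tnfrsf1b by 1.48 ± 0.09 and Ikzf2 by 0.68 ± 0.12, and Ctla4 was at 0.59 ± 0.40 (adjusted p = 0.201).

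Most effector and helper lists held more genes higher than lower with age in Treg, as did the 391 tested genes (192 and 62). As scaled by the authors, none of these lists passed camera. Its adjusted p was 0.147 for effector and memory, 0.237 for Th1, 0.382 for Th17, 0.510 for follicular helper and 0.803 for Th2 genes. Effector and memory genes gave 12 higher, 0 lower and 6 not past (9 and 1 after median centring), with Il18r1 at 1.85 ± 0.12. Th1 genes gave 11 higher, 1 lower and 5 not past (11 and 2), with the inflammatory homing receptor Cxcr3 at 2.30 ± 0.16, the interleukin-18 receptor chain Il18rap at 2.31 ± 0.19 and Ifng at 0.94 ± 0.22 (0.41 and 1.53 by title series, and 0.21, not past, after quantile normalization), and with Lta at −1.0 ± 0.08. Follicular helper genes gave 6 higher, 0 lower and 5 not past (6 and 2), with Maf at 1.82 ± 0.15 and the costimulator Icos at 1.43 ± 0.14. Th17 genes gave 8 higher, 0 lower and 4 not past (9 higher adjusted over the list alone; 5 and 0 after median centring), with Batf at 1.83 ± 0.10 and Ahr at 1.53 ± 0.16. Th2 genes gave 4 higher, 3 lower and 2 not past (3 and 3). Il17a rose by 1.03 ± 0.43 (adjusted p = 0.0408), a call lost when any 1 of young Treg replicates 2, 3, 5, 6 and 7 or aged Treg replicates 2, 4 and 5 was left out, and lowest, at 0.62 (adjusted p = 0.130), without aged Treg replicate 4. It was also lost with values under 20 set to 20 (0.69), after median centring (0.70) and after quantile normalization (0.18).

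Cytokine genes gave 11 higher, 1 lower and 8 not past (10 and 4 after median centring). As scaled by the authors, none of the lists in this paragraph passed camera (adjusted p from 0.754 for cytotoxicity to 0.918 for chemokine receptor genes). Besides Il21 and Ifng, Il10 rose by 1.67 ± 0.55 (adjusted p = 0.0116), with 0.71 and 2.79 by title series, and did not pass after quantile normalization (1.10) or without aged Treg replicates 4 and 6 (1.39, adjusted p = 0.0536). Cxcl3 was at least 5.24-fold higher. The interleukin-1 antagonist Il1rn (3.03 ± 0.28), the decoy receptor Il1r2 (4.03 ± 0.38), the interleukin-13 receptor Il13ra1 (3.32 ± 0.24) and complement C3 (3.25 ± 0.42, floored 2.07) were among the largest increases. Cytotoxicity genes gave 6 higher, 0 lower and 8 not past, before and after median centring, with the chemokine genes Ccl5 at 3.41 ± 0.39, Ccl4 at 2.56 ± 0.48 (floored 2.08; 1.55 and 3.65 by title series) and Xcl1 at 1.65 ± 0.28. Their factor Eomes was at 0.01 ± 0.39 (adjusted p = 0.972) with opposite values by title series, −1.17 in DP20323 and 1.31 in DP182. Co-inhibitory genes gave 6 higher, 1 lower and 6 not past (5 and 2), with Pdcd1 at 1.59 ± 0.23. Chemokine receptor genes gave 8 higher, 3 lower and 6 not past (6 and 3), with the fractalkine receptor Cx3cr1 at least 3.19-fold higher. Cd4 rose by 0.34 ± 0.05 but stood at 0.02 after median centring, and Tnf was at 0.32 ± 0.18 (adjusted p = 0.129), or 0.47 without aged Treg replicate 6 (adjusted p = 0.0188).

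Of class II genes, H2-Ab1 rose by 3.55 ± 0.51, H2-Aa by 3.48 ± 0.51 and Cd74 by 2.75 ± 0.30. Of 14 B cell genes, 10 were higher and none lower (9 and 0 after median centring; 9 and 1 without aged Treg replicates 4 and 6), with the inhibitory receptor Cd22 at 1.78 ± 0.15. Of 4 plasma cell genes, 3 were higher (1 higher and 1 lower after median centring), and of 4 monocyte genes 2, with Cybb at 1.69 ± 0.12. Of 3 neutrophil genes 1 was higher, Il1r2, and of 6 dendritic cell genes 2 were higher and 1 lower (2 and 2). None of 4 natural killer cell genes, the CD8 gene or 2 erythroid and platelet genes passed, and both stroma genes were lower.

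Of the 254 calls, 253 had the same direction in both title series (r = 0.841 across genes). The groups did not overlap for 139 of the called genes and for 22 of the 24 largest, all except C3 and Ccr9. Those genes were chosen by these same values. Of all 391 tested genes, called or not, 139 did not overlap, where the chance share for a single gene is 0.117%. Without aged Treg replicates 4 and 6, 175 genes were higher and 68 lower, and 232 calls remained. The higher share was 75.6% as scaled by the authors, 49.6% after median centring, 88.5% after centring on Abcf1 and 44.0% after quantile normalization, with 14, 8 and 34 directions turned.

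**Figure D3:**
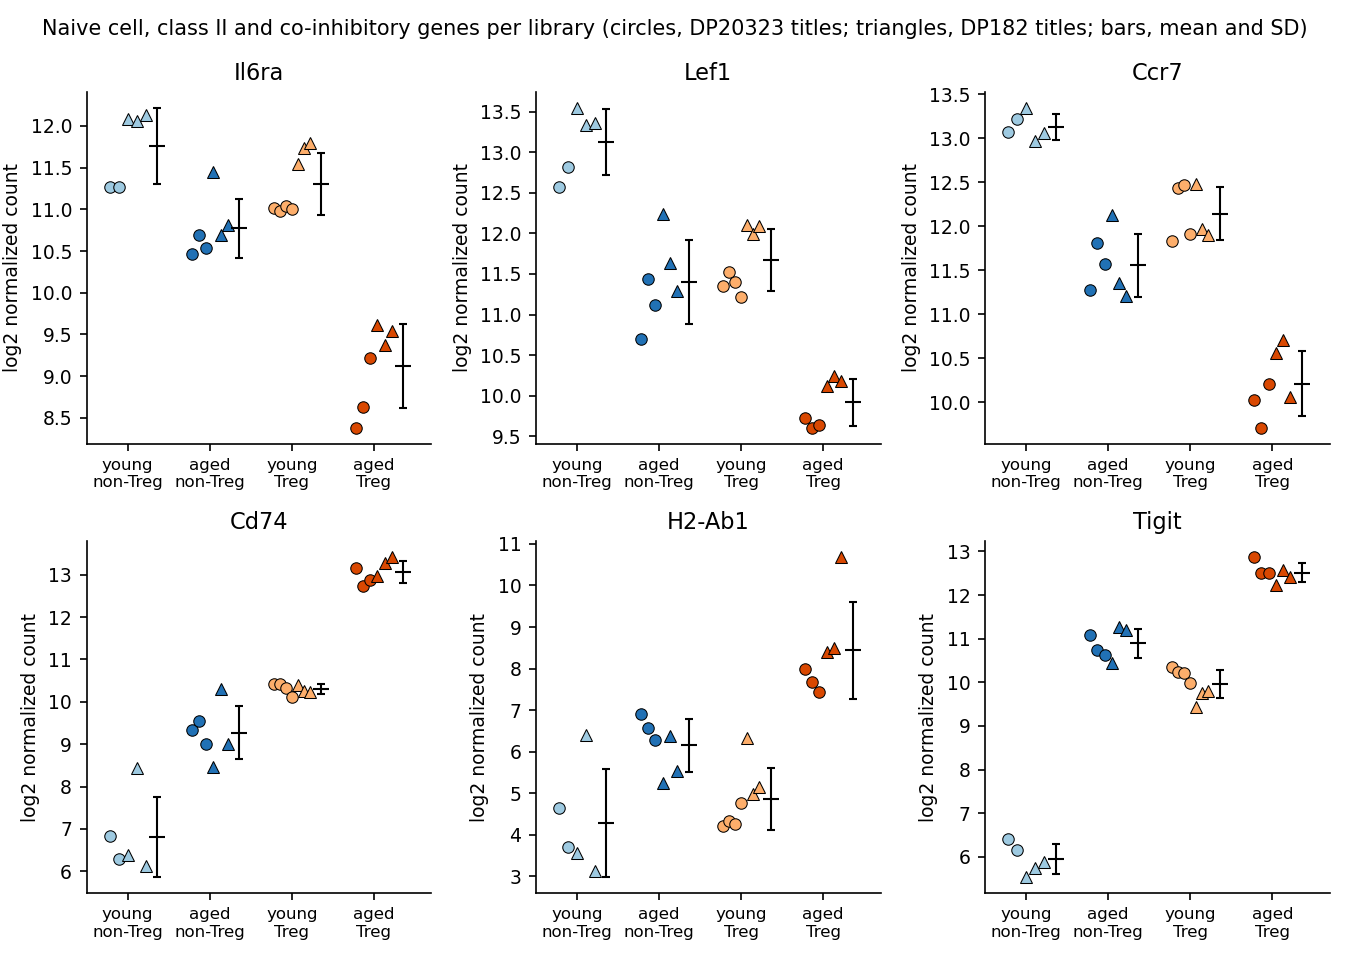
Log2 normalized counts of Il6ra, Lef1, Ccr7, Cd74, H2-Ab1 and Tigit in each library, by group (circles, DP20323 titles; triangles, DP182 titles; bars, mean and SD). With age Il6ra, Lef1 and Ccr7 are lower (−2.22, −1.79 and −1.94 in Treg) and Cd74, H2-Ab1 and Tigit higher, and H2-Ab1 is highest in aged Treg replicate 6 (10.68).

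Aged against young non-Treg asked what ageing changed in the remaining CD4+ cells. The chemokine genes Ccl3 and Ccl5 rose 127-fold (6.98 ± 0.59, floored 6.71, n = 6 against 5) and 82.7-fold (6.37 ± 0.42), Eomes 30.9-fold (4.95 ± 0.43), Tigit 30.2-fold (4.92 ± 0.16), Il21 16.6-fold (4.06 ± 0.32) and Ifng 11.1-fold (3.47 ± 0.24). Against young libraries that were all below 20, Ccl4 rose at least 54.1-fold, Lilrb4a at least 20.5-fold, Pdgfb at least 18.5-fold, Gzmb at least 15.5-fold, Il1r2 at least 13.7-fold and Il10 at least 11.2-fold. Of 391 genes, 216 were higher and 46 lower (limma), 131 and 16 by 2-fold or more.

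Effector and memory genes gave 15 higher, 0 lower and 3 not past (14 and 2 after median centring; camera adjusted p = 0.0081, but adjusted p = 0.507 with an estimated correlation). They included the memory marker Cd44 (1.73 ± 0.09) and the integrins Itgal (1.15 ± 0.06) and Itga4 (1.35 ± 0.08). Th1 genes gave 14 higher, 0 lower and 3 not past (10 and 3; camera adjusted p = 0.0228, but adjusted p = 0.507 with an estimated correlation). Runx3 stood at 3.92 ± 0.28, Cxcr3 at 2.95 ± 0.17 and the interleukin-12 receptor Il12rb1 at 2.62 ± 0.18. Cytotoxicity genes gave 10 higher, 0 lower and 4 not past (9 and 0). Follicular helper genes gave 9 higher, 0 lower and 2 not past (8 and 3; camera adjusted p = 0.0576), with Cxcr5 at 3.59 ± 0.21, Maf at 3.57 ± 0.17 and Sh2d1a, which encodes the adaptor SAP, at 1.66 ± 0.11. Th17 genes gave 9 higher, 0 lower and 3 not past (6 and 1), with Batf at 1.75 ± 0.11, Ahr at 1.61 ± 0.18 (0.25, not past, after quantile normalization) and Il17a at least 1.74-fold higher (adjusted p = 0.0035). The call of Il17a was lost after median centring (0.80, adjusted p = 0.107). By title series it was at least 4.12-fold higher in DP182, whereas in DP20323 only 1 of 3 aged and 0 of 2 young libraries reached 20. Th2 genes gave 2 higher, 4 lower and 3 not past (2 and 6), with the interleukin-4 receptor Il4ra at −1.23 ± 0.14 and Il17rb at −1.21 ± 0.22.

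Treg identity genes gave 17 higher in aged non-Treg, 1 lower and 5 not past (16 and 6 after median centring, 14 and 6 after quantile normalization; camera adjusted p = 0.0131, but adjusted p = 0.507 with an estimated correlation). Foxp3 was at −0.30 ± 0.35 (adjusted p = 0.480), but passed as lower after median centring (−1.16, adjusted p = 0.0061) and quantile normalization (−1.62). Ikzf2 rose 8.97-fold (3.17 ± 0.13), Ctla4 by 2.96 ± 0.44 (1.90 and 3.84 by title series), Tnfrsf4 by 2.04 ± 0.12 and the ectonucleotidase Nt5e by 1.91 ± 0.09. The lower member was Ccr8, which reached 20 in 2 of 5 young and none of 6 aged non-Treg libraries, so no fold is given, and its call was lost with values under 20 set to 20 (adjusted p = 0.0908). Il2ra was at 0.29 ± 0.28 (adjusted p = 0.370), at 0.61 without young non-Treg replicate 4 (adjusted p = 0.019), and at −0.86 after quantile normalization. Co-inhibitory genes gave 11 higher, 1 lower and 1 not past (7 and 2; camera adjusted p = 0.172, adjusted p = 0.0068 after median centring and adjusted p = 0.507 with an estimated correlation), with Pdcd1 12.5-fold higher (3.64 ± 0.25) and Entpd1 11.9-fold (3.57 ± 0.23).

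Naive and central memory genes gave 6 lower, 0 higher and 5 not past (11 lower after median centring; camera adjusted p = 0.000221, but adjusted p = 0.342 with an estimated correlation). Lef1 fell by 1.66 ± 0.13, Ccr7 by 1.57 ± 0.19 and Il6ra by 0.92 ± 0.13. Other large decreases were Card9 (−2.08 ± 0.19), Ifngr2 (−2.0 ± 0.15), the integrins Itga5 (−1.74 ± 0.23, floored −1.63) and Itga6 (−1.21 ± 0.12), Cd55 (−1.68 ± 0.16) and Plaur (−1.86 ± 0.64), and without young non-Treg replicate 2 Plaur was −1.41 (adjusted p = 0.0672). Cytokine genes gave 13 higher, 0 lower and 7 not past (9 and 4), with Csf1 at 3.59 ± 0.18. Chemokine receptor genes gave 10 higher, 3 lower and 4 not past (8 and 5, or 6 and 6 after quantile normalization). Cd4 rose by 0.42 ± 0.05 and Tnf by 0.64 ± 0.20 (adjusted p = 0.0076), but both directions turned after median centring, to −0.45 and −0.23, and after quantile normalization, to −0.06 and −0.31.

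Among other-cell markers, 8 of 14 B cell genes were higher and none lower (6 adjusted over the list alone; 3 and 1 after median centring), with Cd22 at 3.21 ± 0.17 and Cd74 at 2.47 ± 0.32. Monocyte genes gave 2 higher and 1 lower of 4 (1 and 1), with Cybb at 3.71 ± 0.14, and dendritic cell genes 3 higher of 6 (1 and 2), with Cd80 at 3.48 ± 0.21. Plasma cell genes gave 3 higher of 4 (1 and 1), neutrophil genes 1 higher of 3 (1 and 1) and natural killer cell genes 2 higher of 4 (1 and 0). Stroma genes gave 1 higher and 1 lower (0 and 2), and neither erythroid and platelet gene passed. The CD8 gene Cd8b1 fell by 1.06 ± 0.26. Of the 262 calls, 261 had the same direction in both title series (r = 0.922 across genes). The groups did not overlap for 165 of the called genes and for 20 of the 24 largest, all except Ccr8, Plaur, Itga6 and Il17rb. Those genes were chosen by these same values. Of all 391 tested genes, called or not, 166 did not overlap, where the chance share for a single gene is 0.433%. The higher share was 82.4% as scaled by the authors, 33.8% after median centring, 88.8% after centring on Abcf1 and 36.3% after quantile normalization, with 78, 0 and 57 directions turned.

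**Figure D4:**
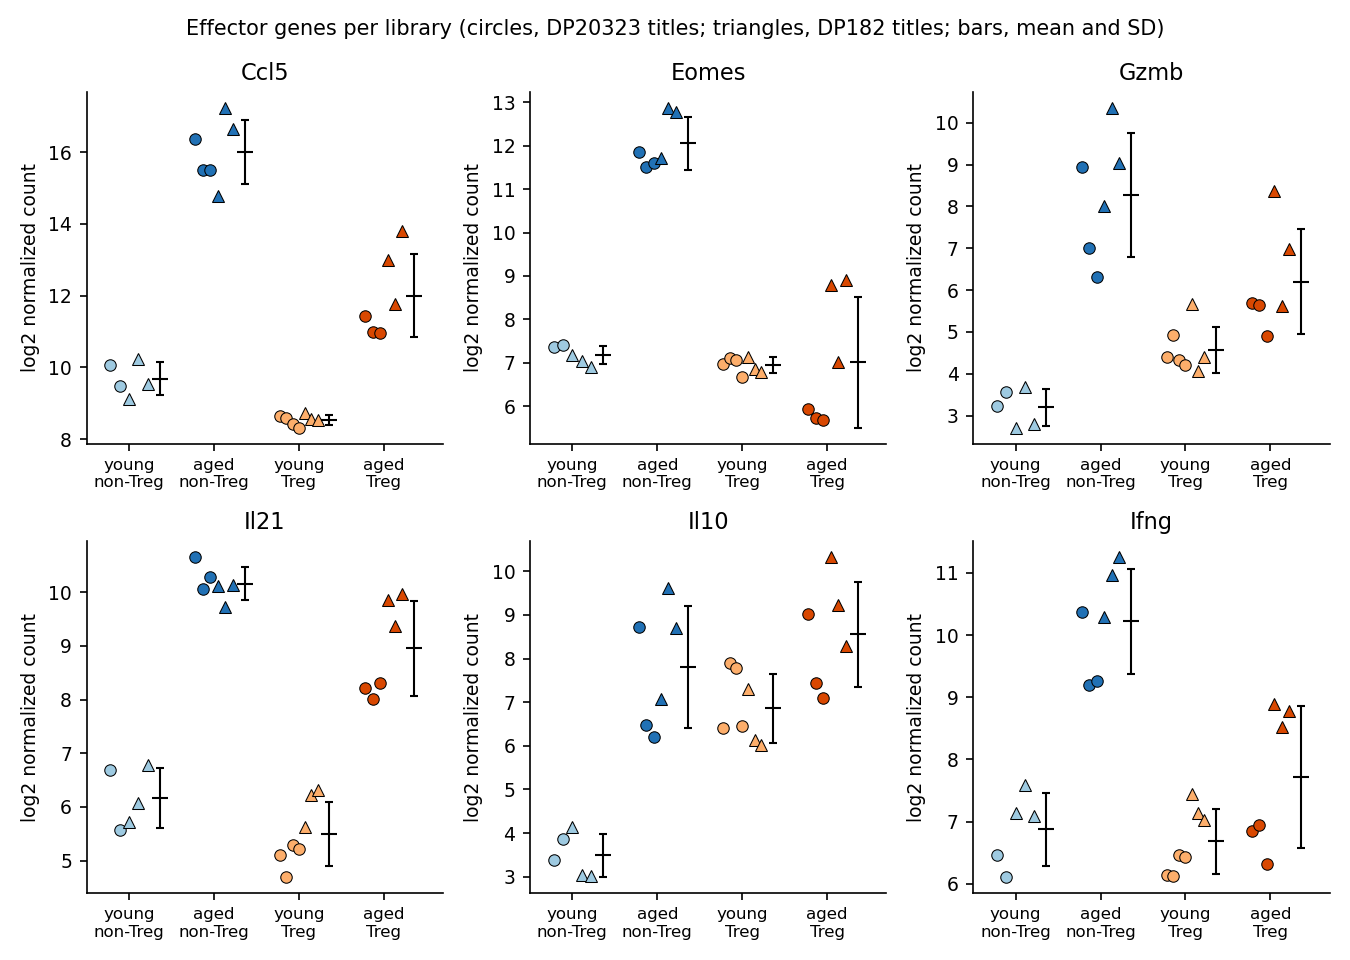
Log2 normalized counts of Ccl5, Eomes, Gzmb, Il21, Il10 and Ifng in each library, by group (circles, DP20323 titles; triangles, DP182 titles; bars, mean and SD). All 6 genes are higher in aged than in young non-Treg, and Eomes in aged Treg splits by title series (log2 fold change −1.17 in DP20323 and 1.31 in DP182).

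The difference between both age effects asked which genes age changed unlike in Treg and non-Treg. It passed for 156 genes (limma interaction), with the age effect lower in Treg for 125 of them and higher for 31. The gain of Ikzf2 was smaller in Treg by 2.48 ± 0.18, that of Csf1 by 2.65 ± 0.24 and that of Cybb by 2.03 ± 0.18, and Ikzf3 (−2.15 ± 0.14) and Pou2f2, the lymphoid factor OCT2 (−1.81 ± 0.12), also differed. The age effect was larger in Treg for Il18r1 (1.73 ± 0.18), Cd81 (1.55 ± 0.18) and the protease Ctss (0.59 ± 0.09). It also passed as larger in Treg for Ccr8 and the complement protease C1ra, with no size given, since Ccr8 lay below 20 in all 6 aged and C1ra in all 11 non-Treg libraries. Eomes, chosen after its values were seen, had a difference of −4.94 ± 0.58 (adjusted p = 6.36e-07).

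For this difference, effector and memory genes gave 12 lower, 1 higher and 5 not past (9 and 4 after median centring). In the same order, Th1 genes gave 10, 2 and 5 (8 and 3), cytotoxicity genes 8, 0 and 6 (5 and 1), co-inhibitory genes 7, 0 and 6 (5 and 1), follicular helper genes 6, 0 and 5 (5 and 2) and chemokine receptor genes 9, 1 and 7 (5 and 2). Treg identity genes gave 13 lower, 3 higher and 7 not past (11 and 8), and naive genes 6 lower, 0 higher and 5 not past (3 and 2; 6 and 1 adjusted over the list alone). No list passed camera, the smallest adjusted p being 0.134, as it was for effector, follicular helper and co-inhibitory genes, but 7 lists passed after median centring. With an estimated correlation, as scaled by the authors, the smallest adjusted p was 0.782. Median centring shifted this difference by 0.54, so the higher share of 19.9% became 73.9%, against 32.5% after centring on Abcf1 and 54.2% after quantile normalization. These turned 33, 0 and 10 directions. None was among the 76 genes past 2-fold, which neither centring could turn, since each shifts all genes alike by less than that. All 156 had the same direction in both title series (r = 0.758 across genes), and 124 genes passed in DP20323 alone and 78 in DP182 alone.

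The age effects in Treg and non-Treg resembled each other across the 391 genes (r = 0.689, rho = 0.734; genes are not independent replicates). Both cell types gained 159 genes, where independent calls would give 106 (Fisher's exact test p = 4.40e-28). Both lost 33, where independent calls would give 7.29 (Fisher's exact test p = 1.41e-20). Fisher's test takes genes as independent, which they are not. Both sets of calls also come from 1 fit with a shared estimate of each gene's spread. Its p-values therefore do not measure how far the cell types aged alike. After median centring 77 were gained in both against 32.7, and 121 lost in both against 65.2. Lilrb4a, Il1r2, Il21, Ccl5 and Tigit were among genes gained and Card9, Ccr7 and Lef1 among genes lost in both. In opposite directions, 9 genes passed, 1 of them higher in Treg and 8 higher in non-Treg. After median centring, 6 of the 8 turned in non-Treg, Cd7 (0.21, adjusted p = 0.288) did not pass there and Pou2f2 stayed opposite, while other genes brought the number to 18. Of those, 16 were higher in Treg and 2 in non-Treg, against 11 and 5 after quantile normalization and 2 and 5 after centring on Abcf1. The direction of this split thus depended on the scaling. The gene higher in Treg as scaled by the authors was Ccr8, whose call in non-Treg rested on values below 20 and was lost when these were set to 20. It rose by 1.52 in Treg (adjusted p = 0.0281), a call lost after median centring (1.20, adjusted p = 0.0785) and without young Treg replicate 5 (1.43, adjusted p = 0.0529), young Treg replicate 6 (1.44, adjusted p = 0.0531) or aged Treg replicate 5 (1.45, adjusted p = 0.051). Ikzf3 fell by 1.53 in Treg and rose by 0.62 in non-Treg, the latter turning to −0.25 after median centring. Pou2f2 rose by 1.61 in non-Treg and fell by 0.20 in Treg (adjusted p = 0.038), but its call in Treg was lost without any 1 of young Treg replicates 1, 2, 3, 4 and 7 and aged Treg replicates 1, 2, 4 and 6, at −0.16 to −0.20 (adjusted p = 0.0539 to 0.110), and turned to 0.06 after centring on Abcf1. Another 53 genes passed in Treg alone and 61 in non-Treg alone. These counts became 42 and 80 after median centring, 62 and 34 after centring on Abcf1 and 61 and 76 after quantile normalization. Whether the age effect of each such gene differed between the cell types is the interaction test above.

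**Figure D5:**
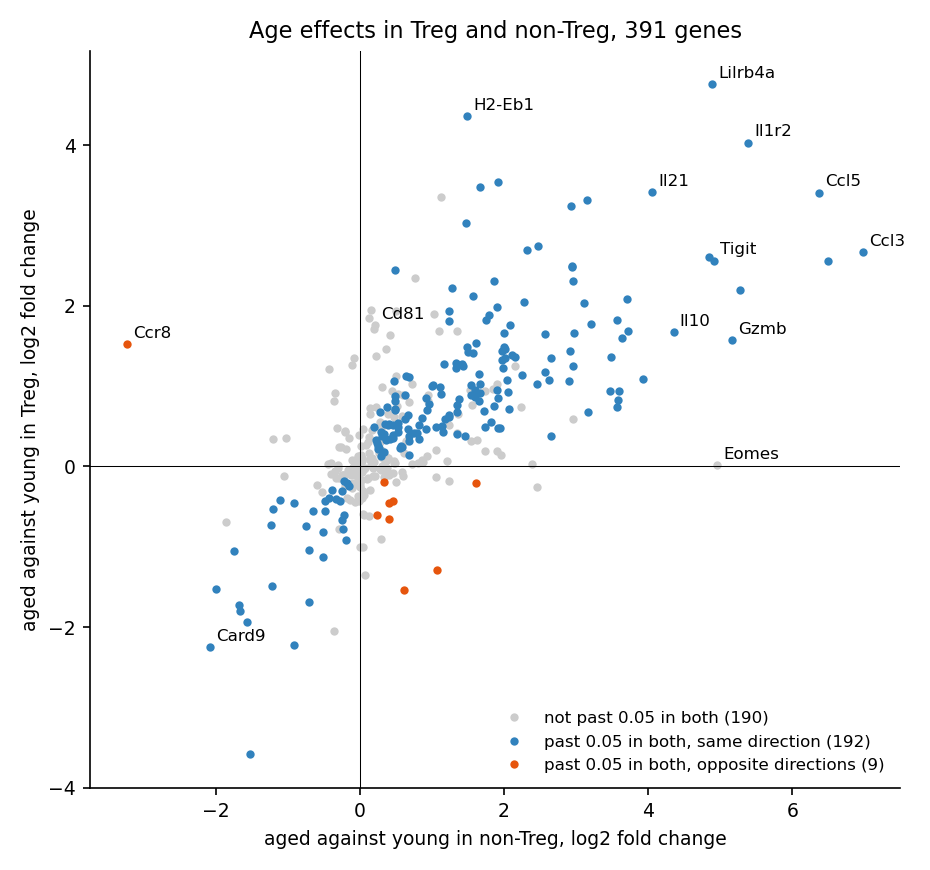
Log2 fold change by age in non-Treg (horizontal) and in Treg (vertical) for the 391 tested genes (1 point each; blue, past 0.05 in both with the same direction, 192; orange, past in both in opposite directions, 9). Ccl5, Ccl3 and Il21 rise in both, and Eomes lies at 4.95 in non-Treg and 0.01 in Treg, with opposite Treg values in the title series (−1.17 and 1.31); the position of Ccr8 in non-Treg rests on values below 20.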

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

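Of the tests in this part, those of Treg cells and of scale in the non-Treg libraries, that of B cells in the Treg gate and that of class II genes without aged Treg replicates 4 and 6 were chosen only after the result was seen. Each count of called genes was set against 100 splits of the same samples, the real one included. In young mice, 1 split, the real one, reached 242 genes for Treg against non-Treg. The highest other gave 196, with 5 Treg and 5 non-Treg libraries relabelled. In aged mice, 1 split reached 277, and the highest other gave 207 with 1 Treg and 1 non-Treg library relabelled. For age in Treg, 1 reached 254, and the highest other gave 210 with 2 libraries relabelled. For age in non-Treg, 1 reached 262. The highest other split there gave 253, and it relabelled 10 of the 11 libraries, so that it nearly mirrored the real one. For the difference of the age effects, 2 splits reached 156: the highest other gave 165 and relabelled 6 Treg and no non-Treg libraries, which left the age effect of non-Treg in place. Splits for this difference shuffled age within each cell type, so they cannot show whether the age effects differ between the cell types. Across the 5 comparisons, in the order above, 93, 89, 89, 87 and 95 of the other splits called no gene (median 0 in each). For the pairwise comparisons the splits argue against chance as the source of the counts. This holds only if each library came from a separate pool, which nothing states.

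Treg identity genes were higher in aged than in young non-Treg libraries, with a median rise of 2.32 on the log2 scale over the 17 of 23 that passed. Treg cells inside the gate, which the CD25 and GITR sort would remove, were tested by Foxp3. Its whole level in aged non-Treg libraries allows 0.784% of Treg cells. The 17 rises, chosen by these same values, need a median of 22.8% (95% interval 10.8 to 33.2, range 3.44 to 409). Members needing most were Gzmb (409%), Entpd1 (63.5%) and Il10 (56.1%). These also belong to the cytotoxicity, co-inhibitory and cytokine lists, so the Treg identity list does not hold Treg genes alone. Others needed little, as Ebi3 (3.44%), Tnfrsf9 (4.41%) and Cd83 (5.17%). As even the lowest need lay above the Foxp3 share, this argues against Treg cells in the gate as the whole source of those 17 rises. A higher scale of the aged non-Treg libraries was tested by median centring over all 23 members: 16 passed as higher and 6 as lower. A shared factor alone would leave at most 3 higher, if genes vary independently. So 1 factor shared by all genes does not account for the list's changes as a whole. Genes across the panel also passed both ways after that centring (33.8% of all calls higher), so a count above 3 does not set this list apart. Unlike the panel's, the list's calls were mostly higher. Camera compared the list with the other genes, with an adjusted p = 0.0131 as scaled by the authors but adjusted p = 0.507 with an estimated correlation. The median of all 23 fell from 1.496 to 0.63 (standard error 0.49), so for the list as a whole a rise and a higher scale cannot be told apart, as its members spread too widely. A hypothesis that stays open, untested, is that aged CD4+ cells in the non-Treg gate may express these genes without Foxp3.

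Aged Treg replicate 4 had raised low values: its lower quartile was 7.17, where the nearest library of its group had 4.59. Of 78 genes under 20 in all other libraries, 83.3% reached 20 in this one, as a background added to most probes would give. It was not equal on every probe, since the other genes stayed under 20 and the lowest count of this library was 4. Cells of 1 other type were tested by their marker lists. The highest median excess, that of natural killer cell genes, lay at −0.28 (standard error 0.79) relative to those 78 genes, whose own median excess was 3.80, and this argues against 1 other cell type as the source. No other explanation was tested.

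Class II genes were higher in aged than in young Treg libraries, by a median of 3.51 on the log2 scale over Cd74, H2-Aa, H2-Ab1 and H2-Eb1. Without aged Treg replicates 4 and 6, which carried raised markers of other cells, the median stayed at 3.04 (standard error 0.37 over genes). Each of the 4 genes stayed at 2.72 or more, which argues against those libraries as the source of the rise. B cells, which a CD4 sort would remove, were tested by 13 other B cell genes, of which follicular helper cells share Cxcr5: without both libraries their median was 0.57 (standard error 0.28), and the abundant Cd79b stood at 8.34 against 7.84 in young Treg. Log2 changes of genes with unlike starting levels are not alike, since the same added RNA moves a high value less. In young Treg, Cd79b and Cxcr5 (8.78) started well above H2-Ab1 (4.86) and H2-Eb1 (4.54). Cd74 started higher (10.31) and rose by 2.72, but how much of each gene B cells hold was not measured. The test therefore cannot tell whether B cells were the source, and Cd22 (1.53), Cd40 (1.71) and Ms4a1 (1.07) were higher. Expression of class II genes by aged Treg, or uptake of class II RNA from other cells, may account for the rise, and neither was tested. Cell types other than B cells were not tested as its source either.

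Among 367 groups of values tested for a library far from the rest of its group, 18 were found, and chance alone gives about 1 in 20, or 18. In aged Treg replicate 4, besides the lower quartile, Ccr9 (8.01), Cd40 (8.20) and Lair1 (7.45) were high. In aged Treg replicate 6, H2-Aa (11.07) and H2-Ab1 (10.68) were high. In young Treg replicate 5, Casp1 (8.51) and Ccr6 (9.39) were low and H2-Aa (7.33), H2-Eb1 (6.14) and Irf4 (9.92) high. Tgfbr1 was high in young Treg replicate 6 (10.76). In young non-Treg replicate 3, Casp1 was low (6.57) and Tgfbr1 high (9.42), and in replicate 4 Src was high (4.99). Klrc1 was low in aged non-Treg replicate 1 (6.97), and Ebi3 (6.45) and Il6ra (11.45) were high in aged non-Treg replicate 4.

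The age effect differed between Treg and non-Treg for 156 genes by the interaction test. Among the genes named, it was higher in Treg for Il18r1 (1.73), Cd81 (1.55) and Ctss (0.59), and for Ccr8 and C1ra, whose fitted values (4.75 and 1.96) rest on non-Treg libraries below 20 and were 2.02 and 1.59 with values under 20 set to 20. It was lower in Treg for Eomes (−4.94), Csf1 (−2.65), Ikzf2 (−2.48), Ikzf3 (−2.15), Cybb (−2.03) and Pou2f2 (−1.81). Of the 156 genes left out by the filter, 131 reached 20 in aged Treg replicate 4, against 0 to 34 in the other libraries.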

How the results depend on the processing

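Leaving out aged Treg replicates 4 and 6, setting values under 20 to 20, pairing Treg and non-Treg libraries by their order, and the age effect correlation in each title series were chosen after seeing the data; the rest were planned. The counts of called genes in the 5 comparisons stayed within 1.5 times the reported ones under all alternatives run but 1: with the DP182 titles alone the difference of the age effects passed for 78 genes, with 12 samples fitted. The split into higher and lower moved with the scaling, as given beside each comparison. Leaving out each library in turn gave 233 to 254 genes for Treg against non-Treg in young mice, 260 to 279 in aged mice, 243 to 257 for age in Treg, 252 to 273 for age in non-Treg and 138 to 169 for the difference. In every one of these fits 220, 247, 233, 239 and 129 of the reported calls remained. The correlation of the age effects ranged from 0.675 to 0.697 across them, and was 0.655 without aged Treg replicates 4 and 6, 0.655 with values under 20 set to 20 and 0.646 in the DP20323 titles; the cause was not tested. The log2 difference of Foxp3 ranged from 6.63 to 7.27 in young and from 6.77 to 7.15 in aged mice. Of 239 single gene results, 204 kept direction and side of the threshold in every alternative. Reversals by median centring were Ifng (−0.72) and Tnf (−0.68) for Treg in young mice, and Cd4 (−0.45), Tnf (−0.23) and Ikzf3 (−0.25) for age in non-Treg. Those by quantile normalization were Ifng (−0.83) and Tnf (−0.63) for Treg in young mice, and Il2ra (−0.86), Cd4 (−0.057) and Tnf (−0.31) for age in non-Treg. The reversals by median centring equal the reported values plus the shift of all genes; for quantile normalization the cause was not tested. Pou2f2 for age in Treg turned with Abcf1 centring (0.057), and Eomes for age in Treg turned in the DP20323 titles (−1.17) and without aged Treg replicates 4 and 6 (−0.79), where the cause was not tested. The other single gene changes were 70 calls lost and 17 gained, against 9203 kept; of the lost, 15 were in DP182 and 6 in DP20323 titles alone and 22 with 1 library left out. Of 125 list results, none reversed; 11 calls were lost with an estimated correlation, 14 gained and 1 lost after median centring, 2 gained without aged Treg replicates 4 and 6, 1 gained and 1 lost with no series covariate, and 91 gained and 1 lost with fry, which does not compare a list with other genes. Counts under about 20 limit the rest, since the background is unknown. Nothing states which Treg and non-Treg libraries came from the same pool. Residuals of libraries paired by order correlated across genes by a mean r of 0.184 over 11 pairs (exact one-sided permutation p = 0.0316 over 2592 matchings; −0.107 in the aged DP182 titles). Fitted as a paired replicate block with a random effect, the 5 comparisons gave 253, 285, 254, 261 and 177 genes, with the side of no single gene result changed. A count model and the planned pseudocount of 1 on linear values were not applied, since the values are scaled log2 counts.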

Other observations

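No test in this part was chosen after seeing the results. With age, more of the 391 tested genes were higher than lower in Treg (192 and 62) and in non-Treg (216 and 46). As scaled by the authors, no list in this part passed camera with age. The smallest adjusted p was 0.237 in Treg (class I presentation) and 0.178 in non-Treg (TGF-beta). With age in non-Treg, T cell receptor signalling genes gave 16 higher, 1 lower and 2 not past (2 and 15 after median centring, 5 and 4 after quantile normalization), with the phosphatase Ptpn22 at 1.34 ± 0.08 and Nfatc1 at 1.12 ± 0.08. In aged mice that list gave 3 higher, 11 lower and 5 not past for Treg against non-Treg (1 and 13), and camera's adjusted p = 0.0121 became adjusted p = 0.607 with an estimated correlation. Jak-STAT genes gave 9 higher, 2 lower and 6 not past with age in non-Treg (2 and 11), with Jak3 at 1.24 ± 0.10 and the feedback inhibitor Socs3 at 1.90 ± 0.18. The interleukin-2 target Cish was higher in Treg at both ages (3.16 ± 0.16 in young, 2.32 ± 0.16 in aged mice), where the list gave 10 higher and 2 lower (1 and 12) in young and 7 and 5 (4 and 8) in aged mice. NF-kB genes gave 8 higher, 3 lower and 5 not past with age in Treg (4 and 7), with Nfkb2 at 1.0 ± 0.17 and the adhesion gene Icam1 at 1.15 ± 0.11, and 10 higher, 1 lower and 5 not past with age in non-Treg (2 and 10), with Icam1 at 1.65 ± 0.12. For Treg against non-Treg that list gave 12 higher, 1 lower and 3 not past in young mice (2 and 7), and 10, 2 and 4 in aged mice (8 and 4).

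Interferon response genes gave 9 higher, 3 lower and 5 not past with age in Treg (4 and 6 after median centring) and 11, 1 and 5 in non-Treg (2 and 11). The interferon-induced chemokine Cxcl10 rose by 2.48 ± 0.26 in Treg and 2.94 ± 0.29 in non-Treg. Apoptosis genes gave 7 higher, 3 lower and 3 not past with age in Treg (4 and 5) and 8, 2 and 3 in non-Treg (5 and 8). The inflammasome protease Casp1 rose by 2.09 ± 0.17 in Treg and 3.71 ± 0.19 in non-Treg. Class I presentation genes gave 8 higher and 0 lower of 9 in Treg (3 and 1) and 7 and 0 in non-Treg (1 and 8), where the nonclassical gene H2-Q10 rose by 2.57 ± 0.30. Of TGF-beta genes, the receptor chain Tgfbr1 was higher in Treg (1.37 ± 0.10 in young, 1.85 ± 0.10 in aged mice) and Tgfbr2 lower (−0.90 ± 0.06 and −0.75 ± 0.06), and the list gave 3 higher and 1 lower of 9 in young (1 and 7) and 4 and 3 in aged mice (2 and 4). Of 4 cell cycle and senescence genes, 1 was higher and 2 lower with age in Treg (1 and 3) and 1 and 1 in non-Treg (1 and 3). The only AP-1 list gene in the table, the early activation marker Cd69, did not pass in any of the 5 comparisons (limma adjusted p from 0.428 to 0.940).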
